A study of Homo sapiens with 4 samples.

How the data were processed

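Per the labels, glioblastoma stem-like cells were derived from U-87 MG and grown in a neurobasal medium with EGF, basic FGF and B27. They received vehicle or 10 µM MRS1220 for 24 h under hypoxia. Libraries were made from total RNA with a TruSeq RNA kit and sequenced on an Illumina HiSeq2500. A first run gave reverse reads only, and the same libraries were sequenced again as read pairs; per the series' design text, the authors added the counts of both runs before testing. The labels do not say whether the 2 libraries of a condition came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of replicates is 2 for each condition.

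The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.36, FastQC 0.10.0, TopHat2, DESeq2 and the GRCh38 build. The counting tool, the gene annotation, the strand setting, and the version and settings of the authors' DESeq2 run are not given in the sources used here. Whether the kit or the counting used strand is likewise not stated, so overlapping and antisense genes are treated as uncertain.

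The single file used is the authors' own comparison, with Ensembl gene identifiers. Per the file headers it holds the authors' mean normalized count over all libraries, log2 fold change, SE of the log2 fold change, Wald statistic, p-value and adjusted p for each of 10118 genes. Decimal commas were converted. Checked on all rows, the statistic equals the log2 fold change over its SE, the p-value is the two-sided normal p of that statistic, and the adjusted p is the Benjamini-Hochberg value over exactly these 10118 rows. The lowest mean normalized count is 90.7, so genes under about that level, lowly expressed ones among them, are not analysed here. The deposited SE lies between 0.076 and 0.190, and VEGFA (mean 9746) has an SE of 0.190, as large as that of genes near the lowest mean. Whether the authors shrank the log2 fold changes is not stated; with shrinkage, the unshrunken estimates would be larger than those printed.

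The file does not state which condition is the numerator. The labels letter vehicle as condition C and MRS1220 as condition D, and by default the authors' tool, DESeq2, puts the level that comes later in the alphabet over the earlier one. Positive values are therefore read as higher with MRS1220. This reading is an assumption, and all directions reverse together if it is wrong. The comparison itself is labelled with c before d, an order that could also be read as C over D.

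The analysis planned before the data were examined assumed counts per library and a count-based test. As the table holds only the authors' comparison, the fallback written in that plan was used: the authors' adjusted p under 0.05, with no test of replicates made here. No SD could be computed, no library could be left out, and depth per library is unknown. The precision of each value is the authors' SE, from which 95% intervals of folds were computed.

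Gene symbols came from a table of identifiers and names (9617 of 10118 genes matched). Coordinates, gene types, transcript length and GC content came from GENCODE release 29 on GRCh38, where 10086 genes matched; length and GC content are those of the longest transcript of each gene. By that annotation 9192 genes are protein-coding, 584 processed pseudogenes and 152 antisense genes. Long intergenic non-coding RNA genes number 0, so absence of a gene need not mean a low count. In all, 3262 genes overlap another listed gene.

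The genes named in the text follow a rule fixed before the data were examined. Among genes with a symbol, an adjusted p under 0.05 and a mean of at least 50, the 12 largest increases and the 12 largest decreases were taken. From each of 32 gene lists, also fixed beforehand, up to 4 called members with the smallest p were taken, or the 2 most abundant members where none was called; some genes this rule takes are not reported here. Also named whatever their value were ADORA1, ADORA2A, ADORA2B, ADORA3, ABCC1, NT5E, CA9, VEGFA, CYP1A1, CYP1B1, SOX2, NES, PROM1 and CD44. Other genes named in the text are said to be picked afterwards or are the remaining members of a list whose count is given. For each list with at least 5 members in the table, the median log2 fold change was placed among 10000 random lists of the same size drawn from the same 20 bins of mean normalized count. Adjusted p-values over a list alone were recomputed from the deposited p-values by Benjamini-Hochberg.

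Settings chosen beforehand that the table allowed were adjusted p under 0.01 and under 0.1, an absolute log2 fold change of at least 1, minimum means of 10, 50 and 100, and recomputed adjusted p-values. After the data were seen, these were added: removal of natural splines (5 degrees of freedom each, weighted by the inverse squared SE, which also centres the values) on GC content, on GC content and log10 length, and on both with log10 mean; division of the statistic by its robust spread; protein-coding genes alone; genes without overlaps; list means in place of medians; and random lists matched on GC content (10 bins within each of 5 bins of mean). Adjusted p-values after each were recomputed with the deposited SE. Tested on simulated data with a GC trend on the 10086 genes with a GC value, the uncorrected test recovered 45% of genes changed by 0.5 on the log2 scale and 98% of those changed by 1, with 227 false calls. With the GC spline it recovered 44% and 99%, with 12 false calls. For simulated lists of 15 genes, all 20 shifted by 0.3 lay above percentile 97.5, and 1 of 20 unshifted lists lay outside the central 95%. The simulated GC trend was steeper than the observed one, and the simulated lists carried no GC trend. Simulated noise was independent between genes, with the deposited SE as its spread. These rates therefore check the computation and do not give error rates for the real calls or lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.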

Results

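The study measured messenger RNA in glioblastoma stem-like cells derived from U-87 MG, an established human glioblastoma line. The cells were held under hypoxia for 24 h with either vehicle (0.001% DMSO) or 10 µM MRS1220, an antagonist of the A3 adenosine receptor. The labels give no DMSO content for the MRS1220 libraries, so whether the solvent was matched is not known. Whether 10 µM acts on that receptor alone was not tested. There were 2 libraries per condition, 4 in all, each sequenced in 2 rounds whose counts the authors added. The comparison asks which transcripts differ between antagonist and vehicle in these hypoxic cells. The authors' deposited table gives 10118 genes, with mean normalized counts over the 4 libraries from 90.7 to 194055 and a median of 434. It holds no values per library, so the depth of each library is unknown here, and every error given is the authors' standard error (SE) of the log2 fold change. The table does not say which condition is the numerator. Positive values are read here as higher with MRS1220, and all directions reverse together if that reading is wrong.

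The response was modest in size as deposited. Whether the authors shrank the fold changes is not stated, and if they did, the unshrunken values would be larger. At an adjusted p under 0.05 in the authors' deposited table, 65 genes were higher and 43 lower with MRS1220, and 3 of these 108 genes, all higher, reached an absolute log2 fold change of 1. They were CADM1, which encodes a cell adhesion molecule (log2 fold change 1.14 ± 0.17 SE in the authors' deposited table, adjusted p = 1.83e-08), CYP1B1, a cytochrome P450 monooxygenase (1.09 ± 0.13, adjusted p = 3.10e-13), and AHRR, the repressor of the aryl hydrocarbon receptor (1.08 ± 0.14, adjusted p = 2.76e-10). As folds, the authors' deposited table puts CADM1 at 2.20 times its vehicle level (95% interval 1.75 to 2.75), CYP1B1 at 2.13 times (1.78 to 2.53) and AHRR at 2.11 times (1.74 to 2.57). On GRCh38, CADM1 (ENSG00000182985) spans chromosome 11, 115169218 to 115504957, on the minus strand. CYP1B1 (ENSG00000138061) spans chromosome 2, 38066973 to 38109902, on the minus strand. AHRR (ENSG00000063438) spans chromosome 5, 304176 to 438291, on the plus strand, where it overlaps PDCD6 on the same strand (0.32 ± 0.16 in the authors' deposited table, adjusted p = 0.438).

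In the authors' deposited table SESN2, a stress-inducible sestrin, rose by 0.85 ± 0.15 on the log2 scale (adjusted p = 2.24e-05), and GREM1, a secreted antagonist of bone morphogenetic proteins, by 0.85 ± 0.16 (adjusted p = 6.65e-05). EREG, which encodes the EGF receptor ligand epiregulin and is abundant here (mean normalized count 9509), rose by 0.77 ± 0.14 in the authors' deposited table (adjusted p = 2.98e-05). ARRDC3, an arrestin-domain adaptor, rose by 0.76 ± 0.13, and SPRY2, an inhibitor of receptor tyrosine kinase signalling, by 0.71 ± 0.16 (authors' deposited table, adjusted p = 1.08e-05 and 0.00147). The list of the 12 largest increases in the authors' deposited table was completed by NBPF1 (0.86), H2AC6 (0.79), GPCPD1 (0.75) and MINDY2 (0.73). NBPF1 and the histone gene H2AC6 belong to families of near-identical copies, so reads assigned to them are uncertain.

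Among the 12 largest decreases, ENO3, the muscle-type enolase, led in the authors' deposited table (log2 fold change -0.99 ± 0.18, adjusted p = 2.98e-05), followed by ERF, an ETS-domain transcriptional repressor downstream of ERK (-0.93 ± 0.15, adjusted p = 2.42e-07). The lipolysis inhibitor G0S2 fell by 0.87 ± 0.13 and the transcription factor EBF2 by 0.86 ± 0.15 in the authors' deposited table (adjusted p = 2.22e-08 and 9.39e-06). GJB2, which encodes a gap junction connexin, was at -0.83 ± 0.12 (authors' deposited table, adjusted p = 1.83e-08), or 0.562 times its vehicle level (95% interval 0.477 to 0.663). ENO3 lies on chromosome 17, 4948092 to 4957131, and overlaps PFN1, which also fell (-0.42 in the authors' deposited table), on the opposite strand. ERF lies on chromosome 19, 42247572 to 42255157, and overlaps ENSG00000268643, a gene without a symbol, on the same strand (-0.83 in the authors' deposited table), so the counts of both are uncertain. The other decreases of this size in the authors' deposited table were MZT2B (-0.81), PDXP (-0.79), REX1BD (-0.75), CRACR2B (-0.74), the metallothionein MT1X (-0.72), FAAP20 (-0.70) and EVA1B (-0.69). MT1X and MZT2B have close paralogs, and G0S2, MZT2B, REX1BD and EVA1B each overlap another listed gene, so their counts are uncertain.

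**Figure D1:**
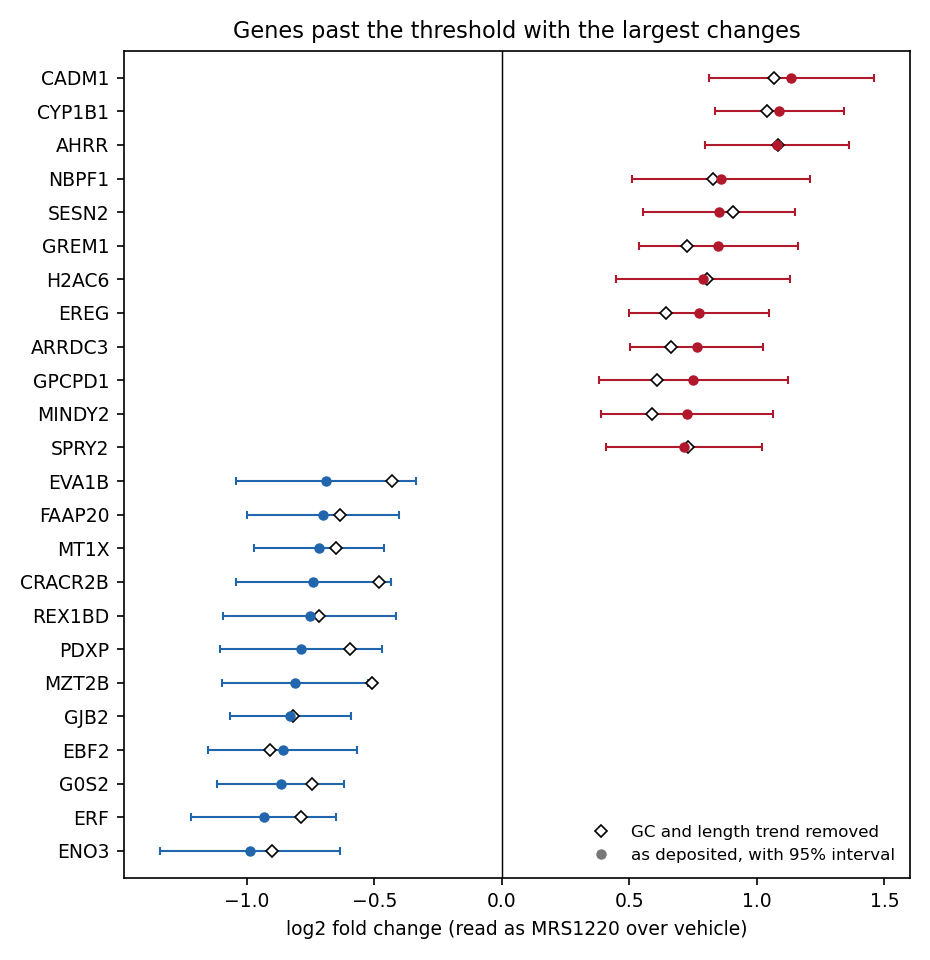
Log2 fold changes (x axis, read as MRS1220 over vehicle) of the 12 genes with the largest increases and the 12 with the largest decreases among genes past an adjusted p of 0.05, 1 gene per line. Filled points are the authors' deposited table with 95% intervals from its SE, and open diamonds are the values after a trend on transcript GC content and length was removed. CADM1, CYP1B1 and AHRR lie beyond 1, while MZT2B moves from -0.81 to -0.51.

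Fold changes in this table fell with the GC content of the transcript, across genes (Spearman's rho -0.37 over 10086 genes, which are not independent replicates), and rose with transcript length (rho 0.33, or 0.26 by rank correlation with GC content held constant). With the mean normalized count they fell as well (rho -0.18), so random lists of abundant genes tend to have negative medians. The median log2 fold change went from 0.13 in the decile of genes with the lowest GC content to -0.15 in the decile with the highest. The highest decile held 24 of the 43 lower genes and 0 of the 65 higher genes. Removing a trend on GC content gave 52 higher and 16 lower genes, and removing one on GC content, length and mean gave 41 higher and 15 lower genes. The share of higher genes among those called was 60.2% as deposited, 76.5% with the GC trend removed, 68.4% with GC content and length removed and 73.2% with the 3-part trend removed; if the reading of the sign is wrong, these are the shares of lower genes. With GC content and length removed, 36 of the 65 higher and 18 of the 43 lower genes kept their call, and of the 24 genes named for the size of their change GPCPD1, MINDY2, MZT2B, CRACR2B and EVA1B did not.

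**Figure D2:**
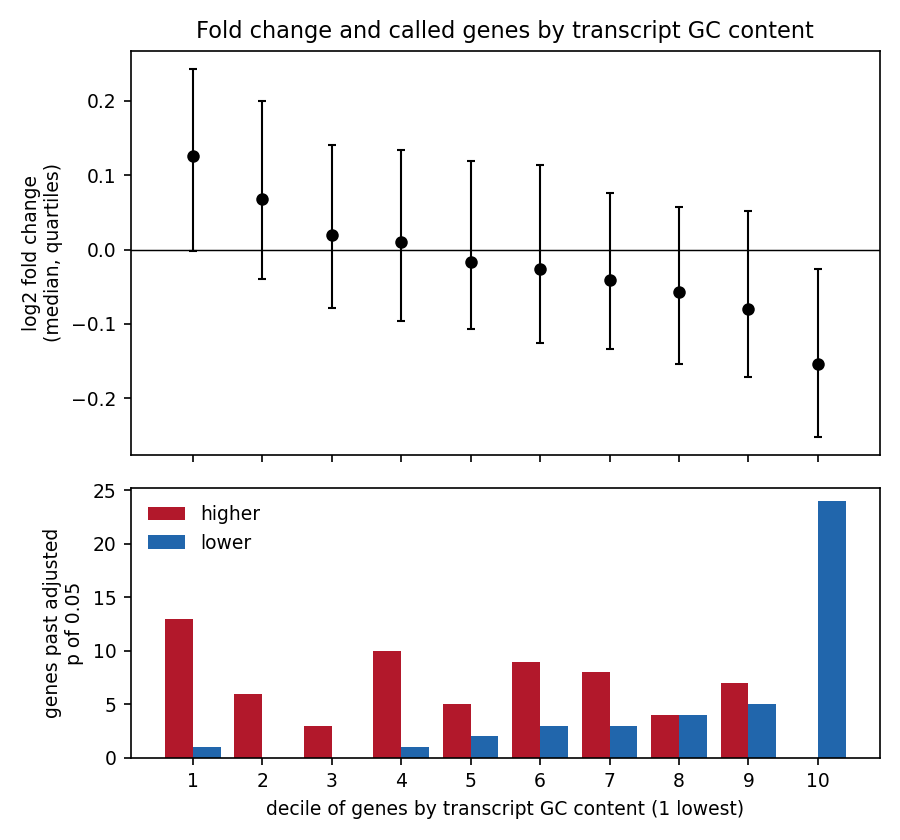
Top, median log2 fold change (y axis, read as MRS1220 over vehicle, bars from the lower to the upper quartile) of the genes in each decile of transcript GC content (x axis). Bottom, the number of genes past an adjusted p of 0.05 in each decile, higher or lower. The median goes from 0.13 to -0.15, and 24 lower genes sit in the last decile.

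Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, stood furthest from the other lists. Of 15 members fixed beforehand, 7 are in the table. Of these 7 members, 4 rose, and the median log2 fold change of 0.54 lay above all 10000 random lists matched on mean count (percentile 100). CYP1B1 and AHRR were joined by NFE2L2, the transcription factor NRF2 (0.66 ± 0.13 in the authors' deposited table, adjusted p = 0.000224), and by the cytokine gene IL1B (0.54 ± 0.13, adjusted p = 0.00577). With the statistic divided by its robust spread, the IL1B call ended (adjusted p = 0.101), while those of CYP1B1, AHRR and NFE2L2 held. Adjusted over the list alone, 5 members were higher and 1 lower, which added TIPARP (0.31 in the authors' deposited table) and SLC7A5 (-0.30), neither past the test over all genes. NQO1 (-0.10) passed neither way.

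Of 25 listed targets of hypoxia-inducible factors, 2 rose and 0 fell, and 5 of the 25 had an unadjusted p under 0.05. ADM, which encodes adrenomedullin, rose by 0.49 ± 0.12, and HILPDA, a lipid droplet protein, by 0.50 ± 0.14 in the authors' deposited table (adjusted p = 0.0158 and 0.0348). Both are among the abundant transcripts, with mean normalized counts of 33254 and 40217 in the authors' deposited table. Both calls ended when the statistic was divided by its robust spread (adjusted p = 0.193 and 0.294). VEGFA (0.22 ± 0.19) and CA9 (-0.06 ± 0.12) did not pass in the authors' deposited table, with adjusted p = 0.734 and 0.889. Adjusted over the list alone, 3 members were higher. The list's median was 0.02, at percentile 99.6 of random lists matched on mean count and at percentile 97.1 when these were matched on GC content as well. Among 18 glycolysis genes no member passed, over all genes or adjusted over the list alone, and none reached an unadjusted p under 0.05; the list's median was -0.04 (percentile 90.4), with GAPDH at -0.15 and LDHA at -0.05 in the authors' deposited table.

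Among lists of energy and lipid metabolism, those of oxidative phosphorylation and fatty acid synthesis had low medians, and none of the 4 lists held a call over all genes. For the 28 listed nuclear-encoded subunits of oxidative phosphorylation the median was -0.13, at percentile 0.62. Of these members 3 had an unadjusted p under 0.05 and 0 passed the authors' adjusted p. Outside the list, the ATP synthase subunit gene ATP5F1D, picked out afterwards, fell (-0.61 ± 0.15 in the authors' deposited table, adjusted p = 0.00895). That call ended with GC content and length removed (-0.41, adjusted p = 0.319). ATP5F1B was at -0.17 and COX4I1 at -0.12 in the authors' deposited table. The 11 mitochondrially encoded mRNAs had a median of 0.08 (percentile 89.2) and no call, with MT-ND4 at 0.19 and MT-CO3 at 0.06 in the authors' deposited table. The 15 genes of fatty acid synthesis and lipid storage had a median of -0.16 (percentile 0.29), and none of them was above 0. Adjusted over the list alone, 4 of them were lower, namely FASN (-0.41), SREBF1 (-0.37), ACLY (-0.32) and SCD (-0.30), while none passed over all genes in the authors' deposited table. FASN, SREBF1 and ACLY were picked out after their values were seen; FADS1, the most abundant member after SCD, was at -0.15 in the authors' deposited table. Cholesterol biosynthesis showed no call among 19 genes and a median of -0.05 (percentile 51.3), with INSIG1 at -0.18 and FDFT1 at -0.33 in the authors' deposited table. Of those 19 genes, 6 had an unadjusted p under 0.05, a level that 10.7% of all listed genes reached.

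Several stress and inflammatory lists lay above their random lists. Of 16 inflammatory and NF-kappaB targets, 2 rose, IL1B and the cytokine gene LIF (0.65 ± 0.15 in the authors' deposited table, adjusted p = 0.00431), and the median was 0.13 (percentile 99.9). Both calls ended with the robust spread (adjusted p = 0.101 for IL1B and 0.0863 for LIF). The list of the unfolded protein and integrated stress response had 1 riser among 20, SESN2, and 3 adjusted over the list alone, with a median of 0.07 (percentile 99.7). The 16 p53 targets also had SESN2 as their riser, 2 adjusted over the list alone, and a median of 0.11 (percentile 98.2). Of 12 apoptosis regulators none passed over all genes and 1 did adjusted over the list alone, XIAP (0.43 ± 0.14 in the authors' deposited table, adjusted p = 0.143), and MCL1 was at -0.03. The apoptosis median was 0.16 (percentile 99.7), while the mean of 0.10 lay within the range of random lists (percentile 96.5). Heat shock genes had 1 of 13 lower, HSPB1 (-0.47 ± 0.12 in the authors' deposited table, adjusted p = 0.0233), which at a log2 fold change of -0.26 no longer passed once GC content and length were removed (adjusted p = 0.580), and a median of -0.01 (percentile 78.8). None of 13 genes of the NRF2 oxidative stress response passed over all genes, 1 was higher and 1 lower adjusted over the list alone, and the median was -0.09 (percentile 25.3); FTH1 was at -0.30 and FTL at -0.02 in the authors' deposited table. The interferon list had no call among 11 genes, 2 higher and 1 lower adjusted over the list alone, and a median of -0.05 (percentile 22.9), with IFITM3 at -0.24 in the authors' deposited table.

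**Figure D3:**
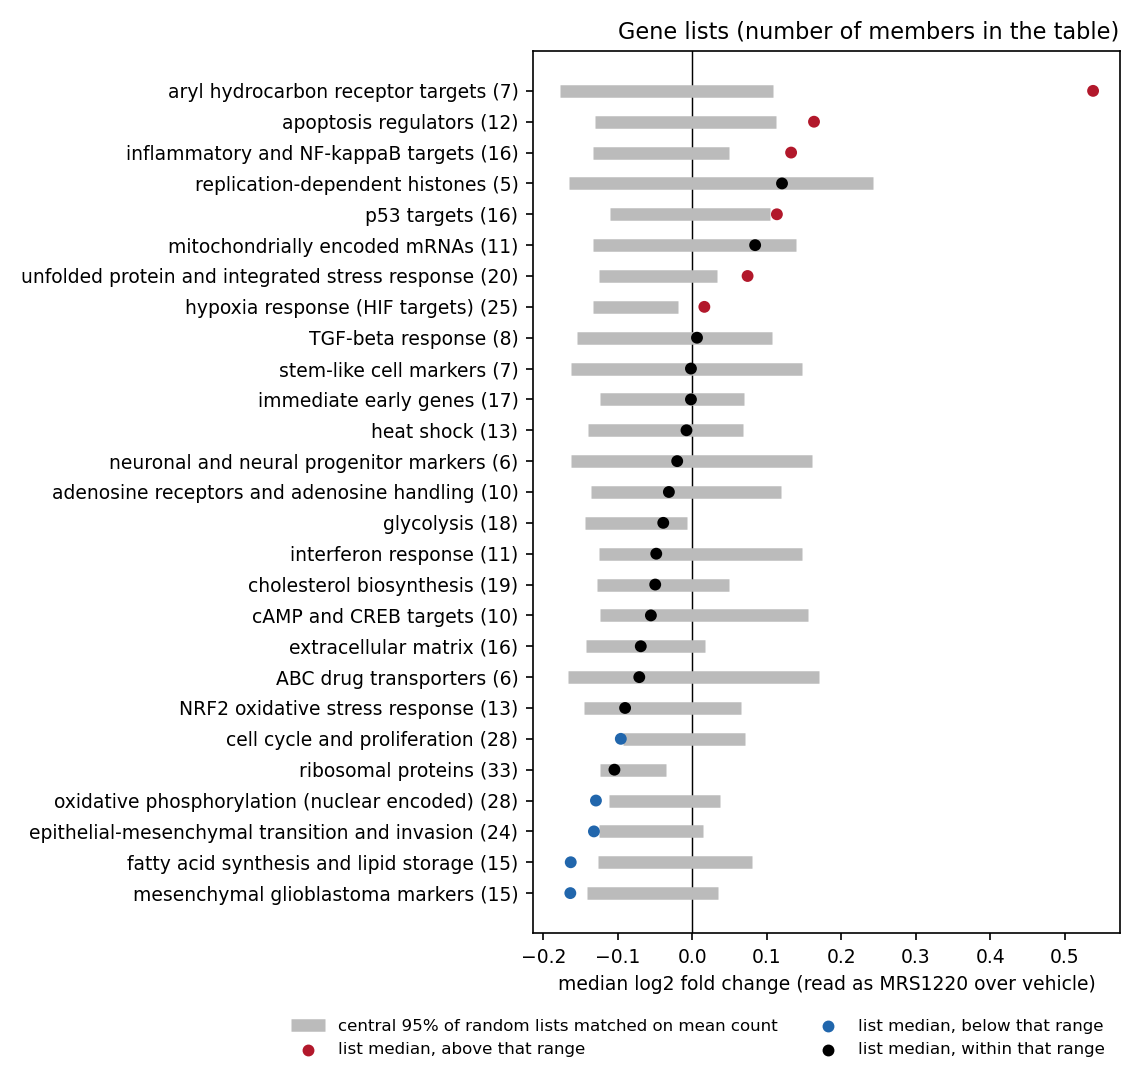
Median log2 fold change (x axis, read as MRS1220 over vehicle) of the 27 gene lists with at least 5 members in the table, 1 list per line, with the number of members in brackets. Grey bars span the central 95% of 10000 random lists matched on mean count. In all, 6 medians lie above and 5 below their bar, and the aryl hydrocarbon receptor targets lie furthest out at 0.54.

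SPRY2 was the riser among 17 immediate early genes (2 higher and 2 lower adjusted over the list alone), whose median was -0.002 (percentile 77.2). Of 8 genes of the TGF-beta response, TGFB1, the ligand itself, fell (-0.51 ± 0.13 in the authors' deposited table, adjusted p = 0.00954), a call that ended with GC content and length removed (-0.38, adjusted p = 0.213). Adjusted over the list alone, 1 of the 8 was higher and 1 lower, and the median was 0.01 (percentile 78.1). The 24 genes of epithelial-mesenchymal transition and invasion had a median of -0.13 (percentile 1.44) but a mean of -0.09 within the range of random lists (percentile 6.77), with none past the authors' adjusted p and 4 at an unadjusted p under 0.05. The median of these 24 genes stayed below the range of random lists with GC content and length removed (percentile 0.09) and with random lists matched on GC content (0.59). The intermediate filament gene VIM was at -0.27 ± 0.11 in the authors' deposited table (adjusted p = 0.276). Mesenchymal glioblastoma markers also had a low median (-0.16, percentile 0.55) over 15 genes, although their mean was -0.06 (percentile 36.0) and their one call was LIF, upward. That call ended with the robust spread (adjusted p = 0.0863), and 6 of the 15 had an unadjusted p under 0.05. The 16 extracellular matrix genes had no call and a median of -0.07 (percentile 57.4), with TNC at -0.06 and COL6A2 at -0.28 in the authors' deposited table. Targets of cAMP and CREB had no call among 10 genes and a median of -0.06 (percentile 18.2), with DUSP1 at 0.05 and PER1 at 0.33 in the authors' deposited table.

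Genes of adenosine receptors and adenosine handling, of drug transport and of the stem-like state gave 1 call. None of 10 listed genes for adenosine receptors and adenosine handling passed or reached an unadjusted p under 0.05, and their median was -0.03 (percentile 46.2). ADORA2B was at 0.07 ± 0.16 and NT5E, which encodes the ectoenzyme CD73, at -0.21 ± 0.11 in the authors' deposited table (adjusted p = 0.909 and 0.484), with AHCY at -0.14. ADORA3, ADORA1 and ADORA2A, with CYP1A1, SOX2 and PROM1, are not among the genes analysed here. Of 6 ABC drug transporters none passed (median -0.07, percentile 25.7), with ABCC1, the multidrug resistance-associated transporter, at -0.19 ± 0.13 (adjusted p = 0.659) and ABCA2 at -0.21 in the authors' deposited table. Of 22 stem-like cell markers fixed beforehand, 7 are analysed here. Among these 7 markers ALDH1A3, an aldehyde dehydrogenase, rose (0.44 ± 0.11 in the authors' deposited table, adjusted p = 0.0126), while NES was at -0.12 ± 0.16 and CD44 at -0.16 ± 0.11 (adjusted p = 0.827 and 0.633). The ALDH1A3 call ended when the statistic was divided by its robust spread (adjusted p = 0.168). The median of the stem-like cell markers was -0.002 (percentile 67.2).

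SOX4, a transcription factor of neural progenitors, rose by 0.67 ± 0.13 in the authors' deposited table (adjusted p = 0.000148) as the one call among 6 listed neuronal and neural progenitor markers (median -0.02, percentile 52.5). Outside that list, the neuronal genes SYN1 (-0.62) and VGF (-0.60), picked out afterwards, fell in the authors' deposited table (adjusted p = 0.00243 and 0.00362). With GC content and length removed SYN1 kept its call (adjusted p = 0.0338) and VGF did not (0.520). Both calls ended with the robust spread (adjusted p = 0.0603 and 0.0774). Lists with too few members for a percentile had no call. These were 4 astrocyte and glial genes (GJA1 at 0.30 and CLU at -0.20 in the authors' deposited table) and 2 endothelial genes (MCAM at -0.18 and ENG at 0.11). Markers of other cell types were 2 leukocyte genes (CD68 at -0.10 and HLA-DRA at -0.24 in the authors' deposited table) and 1 epithelial gene, KRT8 (-0.10), none past the test. No gene of the list of nuclear non-coding RNAs was analysed here.

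Cell cycle genes had no call among 28, over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. Their median was -0.10 (percentile 2.00) and their mean -0.10 (percentile 0.18). The median moved to percentile 9.21 with GC content and length removed, and to 3.76 against random lists matched on GC content. TOP2A was at 0.05 and UBE2C at -0.25 in the authors' deposited table. Of 33 ribosomal protein genes RPL13 fell (-0.42 ± 0.11 in the authors' deposited table, adjusted p = 0.0252), 2 were lower adjusted over the list alone, and the median was -0.10 (percentile 16.1), with the mean of -0.12 below the range of random lists (percentile 1.42). RPL13 shares sequence with processed pseudogenes; it kept its call with GC content and length removed (-0.41, adjusted p = 0.0440) but lost it with a GC trend alone removed (-0.38, adjusted p = 0.0771), with GC content, length and mean removed (-0.36, adjusted p = 0.132) and with the robust spread (adjusted p = 0.255). H2AC6 was the one call among 5 replication-dependent histone genes, whose median was 0.12 (percentile 81.7). The mean of those 5 was 0.27 (percentile 99.5), and the median with GC content and length removed was 0.28 (percentile 99.3), both above the range of random lists.

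Of the 27 lists with a percentile, 11 lay outside the central 95% of their random lists, where 1.35 would by chance if genes were independent. The percentiles describe these 4 libraries and carry no p-value. They cover only the members analysed here, which for some lists are a minority. Examples are 7 of 15 aryl hydrocarbon receptor targets, 7 of 22 stem-like markers, 11 of 24 interferon genes and 6 of 15 drug transporters. With 2 libraries per condition and no values per library, agreement between replicates could not be checked for any gene or list.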

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

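The corrections for GC content, length and mean, the robust spread, the restriction to protein-coding or non-overlapping genes, list means and GC-matched random lists were chosen after seeing the data; the thresholds and minimum means were planned. Against 65 higher and 43 lower genes, an adjusted p under 0.01 left 28 and 27, one under 0.1 gave 98 and 57, and an absolute log2 fold change of at least 1 left 3 and 0 (3 of the 24 genes named for size); these follow from the thresholds themselves. With the GC trend removed the counts were 52 and 16, with GC content and length 39 and 18, and with GC content, length and mean 41 and 15. Dividing the statistic by its robust spread of 1.20 gave 21 and 15. With GC content and length removed, 29 higher and 25 lower calls ended; 27 and 24 of these had moved closer to 0 (MZT2B from -0.81 to -0.51, GPCPD1 from 0.75 to 0.61) and 2 and 1 had not. The robust spread only widens the error. Without overlapping genes the counts were 50 and 30, and with protein-coding genes alone 66 and 43. Minimum means of 10 and 50 removed no gene and say nothing about stability; one of 100 gave 64 and 43. No named gene past the threshold changed direction; over the 7 corrections and filters that could move a value, the 34 named genes past it lost their call in 33 cases, kept it in 194 and were left out in 11. CA9, which did not pass, went from -0.06 to as much as 0.11 with the trends removed. Of 24 genes named for size, 19 to 24 kept their call under the corrections, filters and recomputed adjusted p, except that 17 did without overlapping genes, since AHRR, ENO3, ERF, G0S2, MZT2B, REX1BD and EVA1B were then left out. Among these corrections and filters, IL1B, LIF, ADM, HILPDA, ALDH1A3 and REX1BD lost their call only when the statistic was divided by its robust spread, with ALDH1A3 and REX1BD left out without overlapping genes; GPCPD1, MINDY2, EVA1B, TGFB1, HSPB1 and RPL13 lost theirs there and under at least 1 trend removal. Outside the central 95% of random lists lay 11 of the 27 lists as deposited, 10 with the GC trend removed, 13 with GC content and length or all 3 removed, 9 matched on GC content, 10 by list means and 11 at a minimum mean of 100. With GC content and length removed, mitochondrially encoded mRNAs (percentile 98.7), histones (99.3) and cAMP targets (2.39) moved out of that range and cell cycle genes moved into it. No list outside that range changed sign; within it, median and mean differed in sign for the TGF-beta (0.01 and -0.04), interferon (-0.05 and 0.02), neural progenitor (-0.02 and 0.09), stem-like (-0.002 and 0.01) and immediate early lists (-0.002 and 0.01). Also within it, trend removal turned the medians of glycolysis (-0.04 to 0.03), cholesterol (-0.05 to 0.004), heat shock (-0.01 to 0.04), TGF-beta (0.01 to -0.01), neural progenitor (-0.02 to 0.07), stem-like and immediate early genes (both -0.002 to 0.04). No paired analysis was possible because the table holds no values per library. For the same reason these settings, chosen beforehand, were not run: other normalizations, other tests, low-count filters, leaving out each library, a replicate block, the runs separately, pseudocounts and correlation-aware set tests.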

Other observations

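The groups and genes in this part were picked after their values were seen, as was the test of overlapping genes that share calls. The other tests were set down before their own values were seen, although the trend with GC content and the list medians were already known. All directions rest on reading positive values as higher with MRS1220.

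In a family not covered by the lists, 3 of 5 genes rose. TXNIP, a glucose-responsive inhibitor of thioredoxin and glucose uptake, rose by 0.61 ± 0.12 on the log2 scale in the authors' deposited table (adjusted p = 0.000146), and its arrestin-domain relatives ARRDC3 (0.76) and ARRDC4 (0.59, adjusted p = 0.0216) rose as well. ARRDC2 (0.46) and ARRDC1 (-0.40) did not pass in the authors' deposited table. The ARRDC4 call ended with GC content and length removed (0.55, adjusted p = 0.0635). PPP1R15A, which encodes the stress-induced phosphatase subunit GADD34, rose by 0.69 ± 0.13 in the authors' deposited table (adjusted p = 6.74e-05), and NOTCH2, which has near-identical partial copies in the genome and so uncertain counts, by 0.66 (adjusted p = 0.000167). Next to SESN2 and PPP1R15A, the stress genes DDIT3 (0.59), HERPUD1 (0.52) and ATF4 (0.31) did not pass in the authors' deposited table, with adjusted p = 0.117, 0.0589 and 0.266.

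Of 14 genes around receptor tyrosine kinase and ERK signalling, 3 rose, 1 fell and 10 did not pass, and the median was 0.02 (percentile 82.3). EREG, SPRY2 and SPRED1 (0.56, adjusted p = 0.0315 in the authors' deposited table) rose and ERF fell. SPRED1 lost its call with GC content and length removed (0.44, adjusted p = 0.258). Of 4 metallothionein genes MT1X fell, and MT1F (-0.29), MT1E (-0.21) and MT2A (-0.13) did not pass in the authors' deposited table. Of 3 mitotic spindle organizing genes MZT2B (-0.81) and MZT2A (-0.59) fell and MZT1 (0.36, adjusted p = 0.276) did not pass in the authors' deposited table. With GC content and length removed both calls ended, at -0.51 and -0.50 (adjusted p = 0.0715 and 0.101). Of 132 zinc finger ZNF genes 102 were above 0, against 4718 of all 10118 genes, with 2 past the test and a median of 0.17 (percentile 100). With GC content and length removed the ZNF median was 0.14, still at percentile 100. Of 75 cytosolic ribosomal protein genes 8 were above 0, with 2 lower and a median of -0.12 (percentile 0.485).

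The fall of fold changes with GC content runs across the whole table, beside a rise with transcript length (rho 0.328). The 108 called genes are too few to make a rank trend over 10086 genes. Leaving them out was therefore bound to change little, and rho was -0.368 among the 9978 genes that were not called. Nor is the trend made by transcript length alone, since the rank correlation with length held constant was -0.313. Within cytosolic ribosomal, mitochondrial ribosomal and ZNF genes, families of like function, the rank correlations with GC content were -0.309, -0.541 and -0.464. A trend across the whole table makes such values likely in any large family, whatever its cause, so they do not decide between explanations. A GC-dependent difference between the libraries of the 2 conditions is a candidate explanation. A shift of GC-rich against AT-rich transcripts by the compound itself cannot be told apart from it, because the table has 0 columns of values per library in which replicates of one condition could be compared. With GC content and length removed, 36 of the 65 higher and 18 of the 43 lower genes kept their call; the difference between these shares was not tested.

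The rise of aryl hydrocarbon receptor targets stood apart from that trend. With GC content and length removed the list's median was 0.584, against 0.538 as deposited, so the trend does not account for it. The gene overlapping AHRR moved by 0.320 in the authors' deposited table, less than AHRR did, and no listed gene overlaps CYP1B1. No listed neighbour therefore moved as far as either gene. Genes under the lowest listed mean and long intergenic non-coding RNA genes are not seen. A neighbour sharing some reads could also move less, so shared reads are not excluded. Of the other 2 called members, looked at later, IL1B overlaps no listed gene and NFE2L2 overlaps AGPS (-0.10 in the authors' deposited table) and ENSG00000213963 (0.04), neither of them called. Without CYP1B1 and AHRR the median of the remaining 5 members was 0.31, at percentile 99.99 of random lists. An effect of the compound on this receptor's targets stays open as an untested hypothesis. SLC7A5 (-0.30) and NQO1 (-0.10) were not higher in the authors' deposited table, and CYP1A1 is not analysed here.

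Some called genes overlap another called gene. Of 18 pairs of listed genes with exactly equal values (tolerance 0) in the mean, fold change and p columns, 18 overlap in their spans and 9 include a pseudogene, which is consistent with reads counted for each gene they overlap. The 2 genes of each pair lie on the same strand. Of 769 nested pairs of listed genes, 304 (39.5%) lie on opposite strands, but 0 of the 18 equal pairs do, 11 of them nested. Several equal pairs look like read-through genes, which share a strand by nature, but the 9 with a pseudogene need not. For these pairs, the values argue against counting that ignored strand. Whether the kit kept strand is not stated, so this does not settle called pairs on opposite strands. Shared reads stay open for ERF and for MIF, each with a gene without a symbol on the same strand, and for PFN1 (-0.42 in the authors' deposited table) with ENO3 (-0.99) and KLHL28 (0.68) with TOGARAM1 (0.69), on opposite strands. All 4 pairs share their sign, and with each pair counted once the 108 genes make 104 loci.

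VIM-AS1 (-0.66 ± 0.15, adjusted p = 0.00147 in the authors' deposited table) lies opposite VIM (-0.27 ± 0.11), whose mean of 194055 is the highest in the table.

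The test statistics spread more widely than chance alone gives, with 1078 genes (10.7%) at an unadjusted p under 0.05 where 505.9 would be without any effect.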
